A study of Mus musculus with 15 samples.

How the data were processed

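Poly(A) RNA was sequenced from perivascular fat of the thoracic and the abdominal aorta of control and cKO mice at 11 weeks of age. Per the labels' protocols the tissue was snap-frozen and pulverised, RNA was taken up in TRIzol and purified on RNeasy Micro columns, its quality was read on a Bioanalyzer, and stranded mRNA libraries were made. The authors deposited 1 table of raw counts per Ensembl gene for 43352 genes and 15 libraries. Its values are whole numbers with a different total in each library, so no normalization had been applied. Per the submitters' processing notes the genome build was mm10, and the notes name Salmon, Subread and DESeq2 1.42.1 without a role. Which tool made the counts, the annotation and any strand setting are not given in the sources used here. Genes that overlap others on the opposite strand, such as Prdm16, Gmpr, Mb, Car14, Gldn, G6pdx, Cidea, Elovl3 and Nnat, may thus hold reads of their neighbours. The number 2 of aPVAT cKO was not analysed here. The labels do not give the sex of the mice, the exon flanked by loxP sites, or whether samples with the same number came from the same animal.

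Each column was matched to a sample by depot, genotype and number, and groups were taken from the labels. Gene symbols and locations came from the GENCODE M21 annotation on GRCm38, the mm10 assembly. It held 42462 of the identifiers (97.9%), and the other 890 kept their identifier. Total counts per library were (in M) 63.6, 50.6, 66.9 and 60.6 in aPVAT controls, 65.3, 67.1, 58.0 and 55.6 in tPVAT controls, 68.7, 62.7 and 37.8 in aPVAT cKO 1, 3 and 4, and 68.7, 68.2, 63.5 and 66.0 in tPVAT cKO. No library pair looked like 1 library counted 2 times: within groups chi-square per degree of freedom was 10.5 to 142, and Spearman's rho at least 0.982. Xist lay near the floor in all 15 libraries (0.054 to 0.435 CPM), so no library had a high level. It differed by at most 5.39-fold within a group, a ratio of such low values. The limit for using it as a covariate was 8-fold, so that alternative was not run.

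Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 19645 genes with 99.98% of the counts and removed 23707. Libraries were scaled by TMM. The mean TMM factors were 1.29 and 1.30 in aPVAT cKO and control, and 0.819 and 0.777 in tPVAT cKO and control. One quasi-likelihood model with a mean for each of the 4 groups was fitted to all 15 libraries (common biological coefficient of variation 0.142). Quasi-likelihood F tests compared cKO with control in tPVAT and in aPVAT, aPVAT with tPVAT in controls and in cKO, and the genotype effects between depots (interaction, the aPVAT effect minus the tPVAT effect). P-values were adjusted by the method of Benjamini and Hochberg over all genes tested in a contrast, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. At an unadjusted p under 0.05 there were 5099, 2438, 12028, 11390 and 1738 genes in the 5 contrasts in this order.

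There were 30 gene lists. They covered thermogenic (brown and beige) adipocyte genes, partners of Prdm16, genes selective for white fat, nuclear and mitochondrial genes of the respiratory chain, fatty acid oxidation, lipogenesis, lipolysis and lipid droplets, creatine and calcium cycling, adipocytes of any kind, vasoactive genes, extracellular matrix, interferon response, posterior Hox genes, proliferation, and immediate early genes. The rest held markers of other cells that the samples could include: macrophages, lymphocytes, thymocytes, skeletal muscle, smooth muscle, endothelium, fibroblasts and progenitors, mesothelium, sympathetic neurons, Schwann cells, adrenal cortex, red blood cells, and kidney and lung epithelium. For lung epithelium only Ager was measured, so 29 lists were tested. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with an estimated one, and p-values were adjusted over 145 tests (29 lists and 5 contrasts). With the preset correlation 10, 13, 20, 19 and 12 lists passed in the 5 contrasts, and with the estimated one 1, 2, 3, 3 and 1. Members were counted with p-values adjusted over all genes and adjusted over the list alone. Some genes stand in more than 1 list.

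The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Named genes are Prdm16; in each genotype contrast and in the control depot contrast up to 10 genes with the largest rise and 10 with the largest fall, with adjusted p under 0.05, mean log2 CPM of at least 1, no overlap between groups, and predicted genes left out; up to 4 members of each described list with the smallest p; a fixed panel (Prdm16, Ucp1, Cidea, Elovl3, Dio2, Ppargc1a, Cox8b, Ebf2, Lep, Agt, Retn, Adipoq, Qsox1); the 10 interaction genes with the smallest p; and all genes of a count of 5 or fewer. The white-selective members Hoxc8 and Nnat in aPVAT, Ucp1 and Qsox1 in the interaction, and genes named in the closing section that these rules do not give, were chosen after their values were seen.

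Alternatives were DESeq2 1.42.0 with its own size factors, DESeq2's size factors in edgeR, no low-count filter, only the groups compared in the fit, limma-voom with a quality weight per library, the number as a block, the animal (genotype and number) as a block, and each library left out in turn. For the genotype contrasts the animal was a random block in limma-voom, so a changed call there can also come from the tool. Chosen after seeing the data were the omission of the 2 libraries with over 1% structural RNA, the omission of mitochondrial genes, and the agreement between depots with only the groups compared. For pairing, residual expression was correlated between samples of the same number. Between tPVAT controls and tPVAT cKO all 4 correlations lay at or above 0.107 (up to 0.396), and 3 of the 4 were highest with their own number, so numbers were taken to pair these samples. These are different genotypes, so the number cannot stand for 1 animal there. Blocking by number gave 2392 genes in tPVAT.

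The model was tested on simulated data with 200 changed genes, among 19416 genes for edgeR and 19645 for DESeq2. The spread of the simulated counts was estimated by depot, without regard to genotype. In tPVAT 34.3%, 55.2% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 4 false calls among 124, and in aPVAT 26.9%, 73.1% and 89.4%, with 4 among 130. DESeq2 recovered 90.9% at 4-fold in both, with 28 false calls among 158 and 34 among 178. A list of 30 risen genes gave an adjusted p of 9.12e-76 by camera, and 1 of 87 tests of unchanged lists passed. The simulated genes were drawn independently, so this does not show how the list test behaves where genes of a list vary together. In the real tPVAT libraries, splits other than by genotype gave up to 15 lists past the threshold. Other splits of the same libraries into groups of the same sizes were run through the same model with a fixed seed. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.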

Results

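RNA was sequenced from the fat around the aorta (perivascular adipose tissue, PVAT) of mice aged 11 weeks. PVAT of the chest (tPVAT) resembles brown fat, and PVAT of the abdomen (aPVAT) resembles beige and white fat. Control mice carried Prdm16 alleles with loxP sites, and the cKO mice carried in addition a Cre recombinase driven by the regulatory sequence of the adipocyte gene Adipoq. There were 4 control and 4 cKO libraries of tPVAT, and 4 control and 3 cKO libraries of aPVAT. Total counts ranged from 37.8 M to 68.7 M per library. The smallest library was aPVAT cKO 4. The labels do not say that the samples of a group are separate animals, so p-values measure the spread between these samples. All genes were compared with edgeR, and values are read counts scaled to the library size (CPM, mean ± SD) or log2 fold changes with their standard error (SE).

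Genes of the mitochondrial genome took 34.6% ± 1.28 of the counts in tPVAT controls and 29.9% ± 2.38 in tPVAT cKO (SD, n = 4 each). They took 14.4% ± 1.23 in aPVAT controls (n = 4) and 13.5% ± 0.311 in aPVAT cKO (n = 3). Structural and ribosomal RNA genes took 2.82% of the counts in aPVAT cKO 4 and 1.11% in aPVAT control 2, against 0.0854% to 0.265% in the other libraries. A principal component analysis placed 59.1% of the variance on an axis that parted the depots and 9.39% on an axis that parted the genotypes. The library aPVAT cKO 4 stood apart on the third axis, which held 4.86%.

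Prdm16 encodes the transcriptional coregulator that the study targeted (ENSMUSG00000039410, chromosome 4, 154316125 to 154636873 on the minus strand of GRCm38, the mm10 assembly). It stood at 47.3 ± 6.04 CPM in tPVAT controls (46.4, 41.1, 46.3 and 55.6 in libraries 1 to 4) and at 22.4 ± 1.07 CPM in tPVAT cKO (22.4, 21.2, 22.2 and 23.8). In aPVAT it stood at 23.7 ± 2.22 CPM in controls (26.8, 21.4, 23.3 and 23.4) and at 16.1 ± 1.99 CPM in cKO (15.1, 14.7 and 18.3 in libraries 1, 3 and 4). Prdm16 fell in tPVAT (log2 fold change −1.08, SE 0.0970, adjusted p = 2.22e-06) and in aPVAT (−0.57, SE 0.105, adjusted p = 0.00992), with no overlap between the libraries of the groups. Chance gives such a separation to 2.86% of genes with 4 against 4 libraries and to 5.71% with 3 against 4. The interaction test of the difference between the 2 falls missed the threshold (0.51, SE 0.142, adjusted p = 0.154). A count over the whole gene includes reads outside the part flanked by loxP sites, which the labels do not name, so these values can understate the deletion. The aPVAT call was lost without aPVAT cKO 1 (−0.53, adjusted p = 0.0692), without aPVAT cKO 3 (−0.51, adjusted p = 0.0591), and with only the 7 aPVAT libraries in the fit (−0.55, adjusted p = 0.0739).

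**Figure D1:**
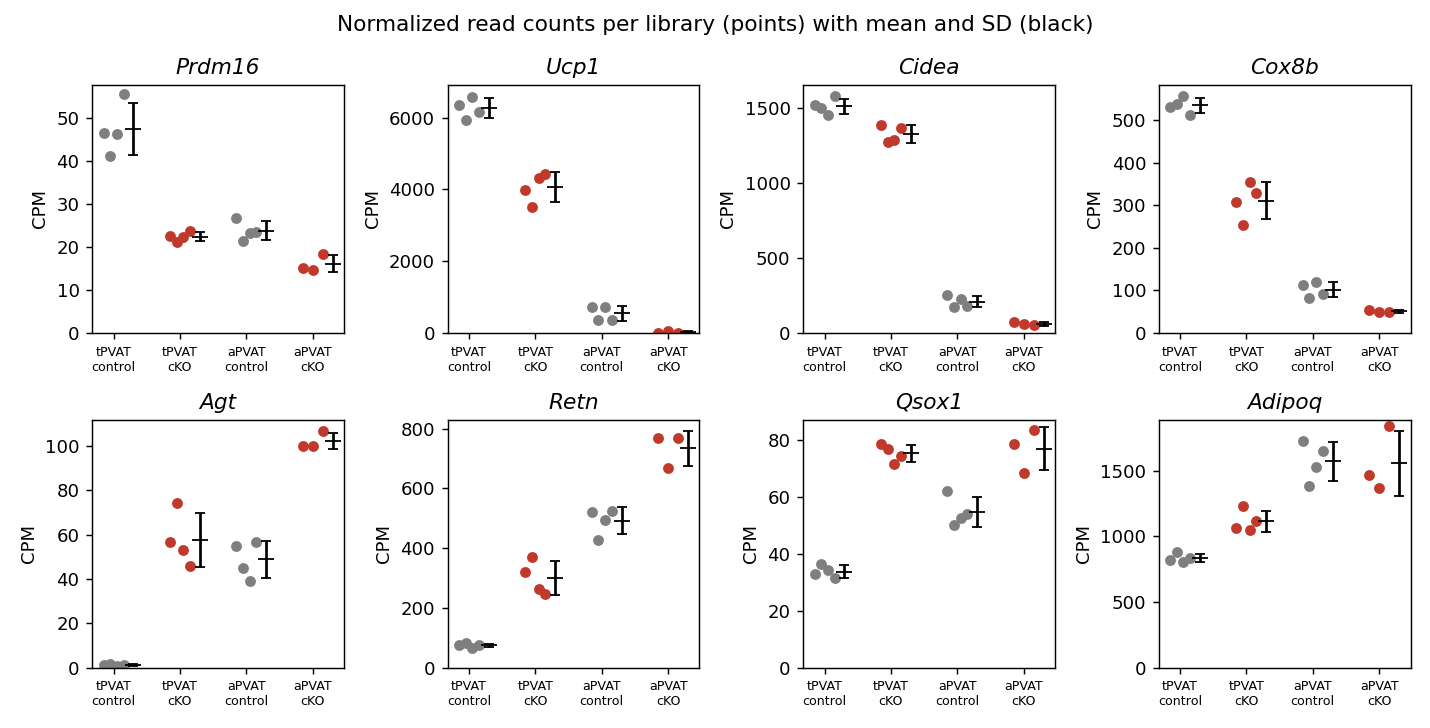
Normalised read counts (CPM, linear axes starting at 0) of 8 genes in the 15 libraries, with 1 point per library and the mean and SD of each group in black. Prdm16 is lower in every cKO library than in every control library of its depot, Ucp1 nears the floor in aPVAT cKO, and Agt in tPVAT cKO reaches the range of aPVAT.

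The tPVAT comparison asked what the loss of Prdm16 in adipocytes changed in the fat of the chest. Agt, the precursor of angiotensin peptides, had the largest rise among the genes named by rule, from 1.31 to 57.6 CPM (log2 fold change 5.44, SE 0.196, adjusted p = 7.99e-11, n = 4 and 4; ENSMUSG00000031980, chromosome 8, 124556534 to 124569706). Reep6, which shapes the endoplasmic reticulum, rose from 35.2 to 328 CPM (3.22, SE 0.164), and Mb, the oxygen-binding myoglobin, rose from 33.7 to 301 CPM (3.16, SE 0.247). Myo5c, an unconventional myosin, fell from 32.1 to 4.07 CPM (−2.98, SE 0.173), and Slc40a1, the iron exporter ferroportin, fell from 21.2 to 5.53 CPM (−1.94, SE 0.108). In all, 2367 of 19645 genes passed (12.05%), 1069 higher and 1298 lower in cKO, of which 260 rose and 114 fell at least 2-fold. With only the 8 tPVAT libraries in the fit 3726 genes passed, more of them higher than lower, and 4080 passed with weights per library.

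The neighbouring fatty aldehyde dehydrogenase genes Aldh3b2 (3.33, SE 0.117) and Aldh3b3 (2.87, SE 0.134) rose together (chromosome 19, 3972328 to 3981646 and 3958645 to 3972103). The melanosome protein gene Mreg (2.76), the creatine transporter Slc16a12 (2.45) and the serpins Serpina3k (3.96, SE 0.729) and Serpina3b (2.39) also rose, as did Hspd1-ps4 (3.11), a pseudogene of Hspd1. Reads of the serpins and of the pseudogene can be shared with close relatives. With animal as a random block, Serpina3k rose by 3.78 with an adjusted p of 0.0637. Further falls were those of Gldn (−2.73), Cpn2 (−1.86), the N-acyl amino acid enzyme Pm20d1 (−1.63), the purine enzyme Gmpr (−1.62), the carbonic anhydrase Car14 (−1.62), the mitochondrial malic enzyme Me3 (−1.49), the thioesterase Acot1 (−1.49) and Kcp (−1.42).

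Genes selective for white over brown adipocytes rose in tPVAT: 10 of 20 measured members rose, none fell and 10 did not pass (12 and 0 adjusted over the list alone). The list had a median of 0.66 (adjusted p = 4.25e-12, and adjusted p = 0.0356 with an estimated correlation). Besides Agt, the members with the smallest p were the serine synthesis enzyme Psat1 (1.96, SE 0.0963), the adipokine Retn (2.0, SE 0.118) and the patterning gene Hoxc8 (1.19, SE 0.116). Thermogenic adipocyte genes fell, with 12 of 34 lower, 2 higher and 20 not passing (13 lower and 2 higher adjusted over the list alone). Their median was −0.45 (adjusted p = 1.57e-05, and adjusted p = 0.284 with an estimated correlation). Cpn2, the nucleotide enzyme Impdh1 (−0.99, SE 0.0873), Acot2 (−0.97, SE 0.141) and Cox8b (−0.78, SE 0.113, from 535 to 311 CPM) led this fall. Ucp1, the uncoupling protein of thermogenic adipocytes, stood at 6257 ± 277 CPM in tPVAT controls and 4059 ± 417 in tPVAT cKO, with no overlap, but missed the threshold (−0.62, SE 0.543, adjusted p = 0.508; ENSMUSG00000031710, chromosome 8, 83290352 to 83298452). With only the 8 tPVAT libraries in the fit the value was −0.61 and the adjusted p 0.000578. The fixed panel also held Cidea (−0.19, adjusted p = 0.348), Ebf2 (−0.20, adjusted p = 0.144; 0.0459 with weights per library), Dio2 (−0.23, adjusted p = 0.607), Ppargc1a (0.19, adjusted p = 0.587), Elovl3 (0.11, adjusted p = 0.809) and Lep (0.71, adjusted p = 0.278), none of which passed. Without tPVAT control 1, Lep passed (1.26, adjusted p = 0.0391).

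Nuclear genes of the respiratory chain fell in tPVAT, with 66 of 76 lower, 1 higher and 9 not passing (71 lower and 2 higher adjusted over the list alone). The list had a median of −0.37 (adjusted p = 5.68e-27, and adjusted p = 0.321 with an estimated correlation). Sdhd of complex II (−0.60, SE 0.0813), Ndufs3 of complex I (−0.55, SE 0.0782) and Atp5e of the ATP synthase (−0.57, SE 0.0794) were among them. Fatty acid oxidation genes fell too, 14 of 25 lower and none higher (18 lower and 2 higher adjusted over the list alone), with a median of −0.36 (adjusted p = 5.55e-07, and adjusted p = 0.464 with an estimated correlation). Examples were Ech1 (−0.69, SE 0.0967), Eci1 (−0.62, SE 0.0749) and Acads (−0.47, SE 0.0853). Of the 13 protein genes of the mitochondrial genome 4 fell and 9 did not pass (9 fell adjusted over the list alone), with a median of −0.30 (adjusted p = 3.3e-05, and adjusted p = 0.464 with an estimated correlation), next to the mitochondrial share of counts of 29.9% in cKO against 34.6% in controls. The 4 were mt-Co3 (−0.41, adjusted p = 0.00493), mt-Co2 (−0.40, adjusted p = 0.0185), mt-Cytb (−0.38, adjusted p = 0.0419; 0.0551 with the number as block) and mt-Nd3 (−0.35, adjusted p = 0.0455). The call of mt-Co2 was lost without tPVAT control 3 (adjusted p = 0.0608) or tPVAT cKO 2 (0.0514), and those of mt-Cytb and mt-Nd3 without any 1 of tPVAT controls 1 to 4 and tPVAT cKO 1 and 2 (adjusted p = 0.0508 to 0.117 and 0.0578 to 0.136). That of mt-Nd3 was also lost without tPVAT cKO 4 (0.0946) or with no low-count filter (0.0508), and that of mt-Cytb with only the 8 tPVAT libraries in the fit (0.0553).

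Lipogenesis genes rose in tPVAT, with 9 of 22 higher, none lower and 13 not passing, also when adjusted over the list alone. The median was 0.21 (adjusted p = 5.21e-05, and adjusted p = 0.284 with an estimated correlation). Me1, which makes NADPH, rose by 1.13 (SE 0.149), the desaturase Scd1 by 1.04 (SE 0.127), and the pentose phosphate enzymes G6pdx and Pgd by 0.68 each (SE 0.0811 and 0.112). Genes of adipocytes of any kind rose as a list, 6 of 18 higher, 1 lower and 11 not passing (9 and 1 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00156, and adjusted p = 0.461 with an estimated correlation). The complement factor Cfd rose by 1.25, Rbp4 by 0.61, Lgals12 by 0.54 and the adipokine Adipoq by 0.41 (SE 0.0944). Qsox1, a disulfide-forming enzyme of the extracellular matrix list and a member of the fixed panel, rose from 33.7 to 75.4 CPM (1.16, SE 0.0787, adjusted p = 1.05e-07).

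Among markers of other cell types, endothelial genes fell as a list with a median of −0.22 (adjusted p = 0.000391, and adjusted p = 0.321 with an estimated correlation). Of 16 measured, 3 fell, none rose and 13 did not pass (8 fell adjusted over the list alone). Among the 3 were the receptors Tie1 (−0.36) and Kdr (−0.32), while Esam (−0.25, adjusted p = 0.036) lost its call without any 1 of 6 libraries, tPVAT controls 1 to 4 and tPVAT cKO 3 and 4 (adjusted p = 0.0608 to 0.102), and with no low-count filter (0.0648). Smooth muscle genes had a median of −0.32 (adjusted p = 0.00173, and adjusted p = 0.519 with an estimated correlation), but only Des fell of 14 measured (−0.45, adjusted p = 0.0213). The call of Des was lost without tPVAT control 2, 3 or 4 or tPVAT cKO 1, 2 or 3 (adjusted p = 0.0508 to 0.061). Sympathetic neuron genes had a median of 0.27 with none of 17 members past the edgeR threshold (adjusted p of the list 0.0154, and adjusted p = 0.680 with an estimated correlation). That call was lost without tPVAT control 2 (adjusted p = 0.119), tPVAT cKO 1 (0.0640) or tPVAT cKO 2 (0.165), and the median was 0.41 without tPVAT cKO 3. Over the 17, Npy stood at 0.53 (adjusted p = 0.0846) and Chgb at 0.52 (adjusted p = 0.145), and both passed without tPVAT control 4 (0.0166 and 0.0359) or tPVAT cKO 3 (0.0285 and 0.0444).

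The other lists did not pass in tPVAT. These were partners of Prdm16 (adjusted p = 0.234, 2 higher and 2 lower of 31, median −0.08, mean 0.00), lipolysis and lipid droplets (0.0703, 6 higher and 1 lower of 18), creatine and calcium cycling (0.212, 1 higher and 4 lower of 10), and vasoactive genes (0.263, 4 higher and 2 lower of 35). Next came extracellular matrix (0.337, 1 higher and 2 lower of 42), posterior Hox genes (0.188, 3 higher of 13), proliferation (0.280, 1 higher of 18), interferon response (0.196) and immediate early genes (0.202). For markers of other cells the adjusted p was 0.907 for macrophages (median −0.02, mean 0.02), 0.660 for lymphocytes, 0.827 for thymocytes, 0.685 for skeletal muscle, 0.639 for fibroblasts, 0.143 for Schwann cells, 0.498 for adrenal cortex, 0.0992 for red blood cells and 0.908 for kidney epithelium. Mesothelial genes had a median of 0.23 with no member past the threshold. In all 10 of 29 lists passed, a number that other splits of the same 8 libraries exceeded (up to 15), so chance could not be excluded for it.

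The aPVAT comparison asked the same question for the fat of the abdomen. Ucp1 fell from 546 ± 210 CPM in controls (724, 363, 731 and 365) to 18.8 ± 25.1 CPM in cKO (5.56, 47.8 and 3.15), a log2 fold change of −4.84 (SE 0.724, adjusted p = 0.00169, n = 4 and 3). With only the 7 aPVAT libraries in the fit that call was lost (−4.83, adjusted p = 0.0979). The lipid droplet protein Cidea fell from 209 to 62.8 CPM (−1.74, SE 0.136; ENSMUSG00000024526, chromosome 18, 67343604 to 67367785), and the cytochrome oxidase subunit Cox7a1 fell from 22.5 to 2.18 CPM (−3.35, SE 0.289). Reep6 had the largest rise among the genes named by rule, from 40.1 to 145 CPM (1.86, SE 0.163, adjusted p = 1.05e-05; ENSMUSG00000035504, chromosome 10, 80329953 to 80336441). Agt rose from 48.9 to 102 CPM (1.07, SE 0.160). In all, 301 genes passed (1.53%), 146 higher and 155 lower, of which 30 rose and 49 fell at least 2-fold.

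Other large falls were those of Cpn2 (−4.58, from 6.65 to 0.270 CPM), Car14 (−3.70), the fatty acid genes Cpt1b (−3.38), Fabp3 (−3.28) and Slc27a2 (−3.13), Fabp3-ps1 (−3.23), whose reads can be shared with Fabp3, and the major urinary proteins Mup17 (−2.38) and Mup14 (−2.22), whose reads can be shared within their family. Further rises were those of the lipase Lipg (1.63), the peroxisomal thiolase Acaa1b (1.59), Angptl8 (1.52), Serpina3j (1.40), Aldh3b3 (1.32), Tlcd2 (1.32), Aldh3b2 (1.26), Marc1 (1.23) and Slc16a12 (1.21). Mup14 lost its call without aPVAT control 4 (adjusted p = 0.0719), aPVAT cKO 1 (0.103), aPVAT cKO 3 (0.0552) or aPVAT cKO 4 (0.106), and Mup17 without aPVAT control 4 (0.0718), aPVAT cKO 1 (0.138) or aPVAT cKO 4 (0.108). Both lost it without the 2 libraries with over 1% structural RNA, aPVAT control 2 and aPVAT cKO 4 (0.0958 and 0.0961). Angptl8 stood at 0.95 without aPVAT cKO 1 and passed.

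Thermogenic adipocyte genes fell in aPVAT, with 18 of 34 lower, none higher and 16 not passing (25 lower and 1 higher adjusted over the list alone). The median was −0.84 (adjusted p = 9.07e-33, and adjusted p = 0.0129 with an estimated correlation). Besides the genes above, the proton channel Otop1 (−1.96, from 39.9 to 10.3 CPM) and Cox8b (−0.998, SE 0.125) fell. Within the fixed panel Dio2 (−1.05, adjusted p = 0.1), Elovl3 (−0.79, adjusted p = 0.196), Ebf2 (−0.20, adjusted p = 0.404), Ppargc1a (−0.06, adjusted p = 0.938), Lep (−0.09, adjusted p = 0.947) and Adipoq (−0.01, adjusted p = 0.973) did not pass. Dio2 passed without aPVAT control 1 (−1.25, adjusted p = 0.0215), with the number as block (0.0330) and with DESeq2 (0.0369). Elovl3 passed with DESeq2 (0.0490). Partners of Prdm16 fell as a list with a median of −0.08 (adjusted p = 0.00622, and adjusted p = 0.227 with an estimated correlation), and 3 of 31 passed. These were the coactivator Ppargc1b (−0.999, SE 0.147) and the nuclear receptors Esrrg (−0.86, adjusted p = 0.0166) and Ppara (−0.83, adjusted p = 0.00215). The list's call was lost without aPVAT control 2 (adjusted p = 0.121), its median was −0.05 without aPVAT cKO 3, and Esrrg was not called without aPVAT cKO 1 (0.120) or aPVAT cKO 3 (0.0892), with weights per library (0.0889) or with animal as block (0.0587).

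Nuclear respiratory chain genes fell as a list in aPVAT with a median of −0.27 (adjusted p = 6.67e-28, and adjusted p = 0.321 with an estimated correlation). Of 76 measured, 6 fell, 1 rose and 69 did not pass, while 63 fell and 1 rose adjusted over the list alone. Examples were Cox7b (−0.41, SE 0.0800), Sdhd (−0.41, SE 0.0885) and Sdhb (−0.47, SE 0.103). Sdhd lost its call without aPVAT control 1 or 3 or aPVAT cKO 3 or 4 (adjusted p = 0.0607, 0.0708, 0.114 and 0.0836). The same libraries and aPVAT cKO 1 ended the call of Sdhb (up to 0.122 without aPVAT cKO 1), and aPVAT cKO 3 or 4 that of Cox7b (0.0694 and 0.0586). Fatty acid oxidation genes fell, 8 of 25 lower and none higher (16 lower adjusted over the list alone), with a median of −0.34 (adjusted p = 6.53e-13, and adjusted p = 0.298 with an estimated correlation). Besides Cpt1b these included Acaa2 (−1.15, SE 0.153) and Acadvl (−0.79, SE 0.132). Lipogenesis genes rose, 8 of 22 higher and none lower (16 higher adjusted over the list alone), with a median of 0.40 (adjusted p = 3.75e-16, and adjusted p = 0.0430 with an estimated correlation). Me1 rose by 0.89 (SE 0.158), Scd1 by 0.72 (SE 0.134), the citrate carrier Slc25a1 by 0.63 (SE 0.119) and Dgat1 by 0.44 (SE 0.0794). Scd1 and Slc25a1 were not called without aPVAT cKO 1 (0.56, adjusted p = 0.0728, and 0.50, adjusted p = 0.0812), nor Dgat1 without the 2 libraries with over 1% structural RNA, aPVAT control 2 and aPVAT cKO 4 (0.33, adjusted p = 0.0590).

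White-selective genes went both ways in aPVAT and did not pass as a list (adjusted p = 0.0992, median 0.09). Of 20 measured, Agt, Psat1 (0.90), Retn (0.58, SE 0.122, adjusted p = 0.0236) and Hoxc8 (0.51) rose, while Nnat (−1.89) and the matrix protein gene Dpt (−0.70) fell. Retn lost its call without aPVAT control 3 (adjusted p = 0.0517), aPVAT cKO 1 (0.108) or aPVAT cKO 4 (0.0899), or without the 2 libraries with over 1% structural RNA (0.0961), and Dpt without aPVAT cKO 1 (0.0864). Hoxc8 and Nnat lost theirs without aPVAT control 3 (0.0678 and 0.0804) or 4 (0.0828 and 0.0810) or aPVAT cKO 1 (0.167 and 0.199) or 3 (0.0836 and 0.159), Hoxc8 also without aPVAT cKO 4 (0.144), without the 2 libraries with over 1% structural RNA (0.0543), with the number as block (0.0782) and with DESeq2's size factors (0.0535), and Nnat without aPVAT control 1 (0.119). Extracellular matrix genes fell as a list with a median of −0.19 (adjusted p = 0.00124, and adjusted p = 0.610 with an estimated correlation), yet the only one of 42 that passed, Qsox1, rose (0.49, SE 0.0828, adjusted p = 0.00522). The call of the matrix list was lost without aPVAT control 2 (adjusted p = 0.0924), and its median was −0.12 without aPVAT control 1.

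Markers of other cells moved in aPVAT mainly as lists, most with no member past the edgeR threshold. Macrophage genes fell with a median of −0.46 (adjusted p = 3.38e-07, and adjusted p = 0.284 with an estimated correlation). None of 19 passed over all genes, while 11 fell adjusted over the list alone, among them the complement gene C1qb (−0.56, adjusted p over all genes 0.0800) and the scavenger receptor Cd163 (−0.63, adjusted p = 0.0846), which passed with DESeq2 (0.0125 and 0.0131). Without aPVAT control 2 C1qb passed (0.0356), as did Cd163 without aPVAT cKO 3 (0.0142). Interferon response genes fell with a median of −0.37 (adjusted p = 7.72e-06, and adjusted p = 0.482 with an estimated correlation), lymphocyte genes with −0.55 (adjusted p = 0.00663, and adjusted p = 0.631 with an estimated correlation) and immediate early genes with −0.31 (adjusted p = 0.00598, and adjusted p = 0.464 with an estimated correlation). No member of these 3 lists passed. Fibroblast genes fell with a median of −0.17, with Dpt the 1 of 15 that passed (adjusted p = 0.00499, and adjusted p = 0.490 with an estimated correlation). Sympathetic neuron genes had a median of 0.20 (adjusted p = 0.0112, and adjusted p = 0.669 with an estimated correlation) and skeletal muscle genes 0.39 (adjusted p = 0.0267, and adjusted p = 0.572 with an estimated correlation), with no member past the threshold in either, and 4 higher for skeletal muscle adjusted over the list alone. The skeletal muscle value rested on aPVAT cKO 3, without which the median was −0.08 (adjusted p = 0.804). Its call was also lost without aPVAT control 2 (0.0571) or 3 (0.0726), and the median was 0.86 without aPVAT control 4 and 0.59 without aPVAT cKO 1.

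Further list calls in aPVAT rested on 1 library. Lymphocyte genes were not called without aPVAT control 4 (−0.06, adjusted p = 0.433), aPVAT cKO 3 (−0.41, 0.0661) or aPVAT cKO 4 (−0.34, 0.263), and stood at −1.02 without aPVAT cKO 1. Fibroblast genes were not called without aPVAT control 2 (0.0778) or aPVAT cKO 4 (0.102), and their median went from −0.09 without aPVAT control 1 and −0.11 without aPVAT cKO 1 to −0.26 without aPVAT cKO 3. Sympathetic neuron genes were not called without aPVAT control 1 (0.216) or aPVAT cKO 3 (0.431), nor immediate early genes without aPVAT control 1 (0.0832). Without the 2 libraries with over 1% structural RNA, the lists of partners of Prdm16 (adjusted p = 0.112), extracellular matrix (0.248), immediate early genes (0.0545), lymphocytes (0.152) and fibroblasts (0.411) were not called. With weights per library the lists of extracellular matrix (0.0933), immediate early genes (0.0523), skeletal muscle (0.202) and sympathetic neurons (0.149) were not, nor was skeletal muscle with the number as block (0.0525) or without mitochondrial genes (0.0567). The lists that did not pass were mitochondrial genome (adjusted p = 0.262), lipolysis (0.201, 2 lower of 18), creatine and calcium cycling (0.638; median 0.04 and mean 0.15, though camera gave the direction as down), adipocytes of any kind (0.235), vasoactive genes (0.173, 2 higher of 35), posterior Hox (0.374, median −0.02, mean 0.07), proliferation (0.0852), thymocytes (0.928), smooth muscle (0.601), endothelium (0.485), mesothelium (0.660), Schwann cells (0.0561), adrenal cortex (0.311), red blood cells (0.601) and kidney epithelium (0.628). In all 13 lists passed, and chance could not be excluded for that number, since other splits of the 7 libraries gave up to 16.

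The number of genes called in aPVAT varied with the libraries and the fit. It was 161 without aPVAT cKO 1, 398 without aPVAT control 2, 605 with DESeq2, and 92 with only the 7 aPVAT libraries in the fit, 90 of them among the 301. In that last fit Ucp1, Mup17, Marc1, Angptl8, Qsox1, Acadvl, Ppara, Esrrg, Dpt, Slc25a1, Dgat1, Me1, Scd1, Sdhd, Sdhb, Cox7b, Hoxc8 and Nnat no longer passed.

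The interaction asked which genes responded differently in the 2 depots on the log2 scale. On that scale Agt rose less in aPVAT than in tPVAT (difference of log2 fold changes −4.38, SE 0.253, adjusted p = 1.45e-07), as did Retn (−1.42, adjusted p = 0.000395), Qsox1 (−0.67, adjusted p = 0.00741) and Aldh3b2 (−2.07, SE 0.161, adjusted p = 7.1e-06). The controls started from unlike levels, so a like rise in CPM gives a smaller log2 fold change in aPVAT. Over libraries, Agt went from 0.873–1.63 to 45.9–74.5 CPM in tPVAT and from 38.9–56.5 to 100–107 in aPVAT. Retn went from 66.9–81.6 to 248–369 CPM in tPVAT and from 426–525 to 667–768 in aPVAT. Mreg (−2.62) rose in tPVAT and did not pass in aPVAT (0.14, adjusted p = 0.812). The thermogenic genes Cidea and Ucp1, which passed in aPVAT alone in the fit of all 15 libraries, had the lower effect there, with a difference of −1.55 for Cidea (SE 0.178, adjusted p = 0.000303) and −4.22 for Ucp1 (SE 0.849, adjusted p = 0.0256). With each depot fitted alone, Ucp1 instead passed in tPVAT and not in aPVAT. The interaction call of Ucp1 was lost without aPVAT control 3 (0.0555), tPVAT control 1 (0.0615), 3 (0.0558) or 4 (0.0606), or aPVAT cKO 1 (0.0581). In all 154 genes passed, 31 with the higher and 123 with the lower effect in aPVAT. The other genes with the smallest p were the lipoprotein genes Apoc2 (−2.75) and Apoc4 (−3.73), which can share reads, the cyclin Ccnd2 (−1.09), the phosphatase Alpl (−0.88), Adgrg2 (−1.26), Pde1b (−1.47) and Gldn (2.85). Ccnd2 averaged 65.9 CPM in tPVAT controls, 263 in tPVAT cKO, 138 in aPVAT controls and 257 in aPVAT cKO. With DESeq2, 350 genes passed.

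Over lists, white-selective genes had the lower effect in aPVAT (median difference −0.77, adjusted p = 1.75e-17, and adjusted p = 0.0146 with an estimated correlation), with 4 of 20 members past the threshold, all lower. Thermogenic genes fell more in aPVAT (−0.41, adjusted p = 4.39e-12, and adjusted p = 0.0550 with an estimated correlation), 9 members lower and 1 higher. Lipolysis genes (−0.16, adjusted p = 0.00013, and adjusted p = 0.284 with an estimated correlation) and macrophage genes (−0.39, adjusted p = 5.51e-06, and adjusted p = 0.321 with an estimated correlation) had the lower effect in aPVAT. Genes of the mitochondrial genome (0.22, adjusted p = 0.000141, and adjusted p = 0.501 with an estimated correlation), smooth muscle (0.34, adjusted p = 0.000101, and adjusted p = 0.464 with an estimated correlation) and endothelium (0.19, adjusted p = 0.000939, and adjusted p = 0.330 with an estimated correlation) had the higher one. The median of lipolysis genes was −0.10 without aPVAT cKO 3 and −0.26 without aPVAT cKO 4. Leaving out aPVAT cKO 4 gave 0.21 for smooth muscle and 0.12 for endothelium, and leaving out aPVAT control 3 gave 0.23 for smooth muscle. In all 12 lists passed, and other draws gave up to 18.

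Genes changed in both depots mostly moved alike. Of the genes called in both, 128 rose in both (7.94 expected), 99 fell in both (10.2 expected) and 0 moved in opposite directions. Of the 301 genes called in aPVAT, 288 had the same sign in tPVAT. The effects correlated across genes with a Pearson r of 0.355 and a Spearman rho of 0.435, though genes are not independent replicates. Reep6, Aldh3b2, Aldh3b3, Slc16a12, Agt, Me1, Scd1, Qsox1, Cpn2, Car14 and Cox8b were named above in both depots. The 227 shared genes became 129 without aPVAT cKO 1, 150 without aPVAT cKO 3 and 73 with only 2 groups in each fit. DESeq2 gave more shared genes, and Pearson's r was far lower without the low-count filter. Both values stand in the section on processing.

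**Figure D2:**
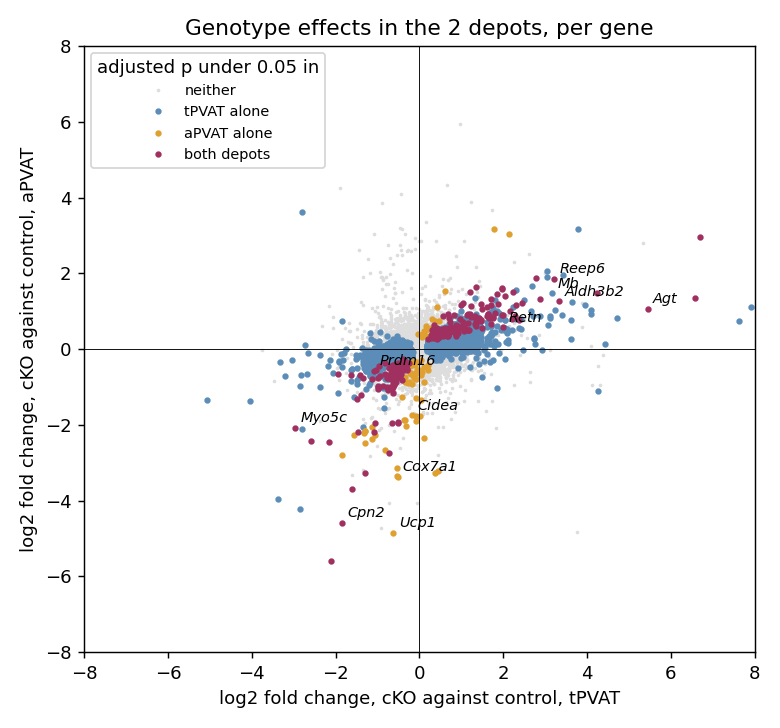
Log2 fold change of cKO against control per gene in tPVAT (horizontal axis) and aPVAT (vertical axis), with 1 point per gene coloured by the depot in which its adjusted p was under 0.05. The 227 genes called in both depots lie in the lower left and upper right of the plot, with Agt far to the right and Ucp1 far down.

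The depot comparison in controls asked how abdominal and thoracic fat differed without the deletion. Posterior Hox genes, which pattern the trunk, were higher in aPVAT (12 of 13 higher, 1 lower, adjusted p = 4.56e-08, and adjusted p = 0.0430 with an estimated correlation), led by Hoxc10 (log2 fold change 6.42, SE 0.230, from 0.257 to 22.5 CPM) and Hoxa10 (5.12, SE 0.220). Thermogenic genes were lower in aPVAT (31 of 34 lower, 2 higher, adjusted p = 2.52e-14, and adjusted p = 0.0430 with an estimated correlation), with Ucp1 at −3.52 (SE 0.597), Elovl3 at −4.35 (SE 0.259), Cidea at −2.85 (SE 0.128) and Dio2 at −2.95 (SE 0.274). White-selective genes were higher (18 of 20 higher, none lower, adjusted p = 3.78e-08, and adjusted p = 0.0543 with an estimated correlation), with Agt at 5.21 (SE 0.195), Retn at 2.71 (SE 0.121) and Lep at 2.34 (SE 0.410). Vasoactive genes were higher as well (21 of 35 higher, 3 lower, adjusted p = 0.000105, and adjusted p = 0.0430 with an estimated correlation). In all 11122 genes passed (56.6%), 5750 higher and 5372 lower in aPVAT, so most members of most lists moved.

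Heart muscle genes had some of the largest differences. The heart myosin gene Myh6 fell from 97.6 CPM in tPVAT controls to 0.196 in aPVAT controls (−8.96, SE 0.413), next to Tnni3 (−4.88), Tnnt2 (−4.35) and Myl4 (−3.96). Mb, of the skeletal muscle list, was also far lower in aPVAT controls (−6.89), but unlike Myl4 it rose in tPVAT cKO. Other genes named by rule were Serpina3b (8.15), Serpina3j (6.23), the complement gene C6 (6.01), Nnat (4.24), the sulfotransferase Sult1e1 (3.77) and Tnr (3.47), all higher in aPVAT, and Gmpr (−4.43), Kng2 (−4.12), Dhrs9 (−3.92) and Acot11 (−3.56), all lower. Respiratory chain genes were lower in aPVAT for 74 of 76 nuclear (adjusted p = 2.04e-34, and adjusted p = 0.284 with an estimated correlation) and 13 of 13 mitochondrial members (adjusted p = 8.52e-12, and adjusted p = 0.284 with an estimated correlation), as were 23 of 25 fatty acid oxidation genes (adjusted p = 1.61e-12, and adjusted p = 0.298 with an estimated correlation). Of 22 lipogenesis genes 17 were lower and none higher (adjusted p = 1.7e-06, and adjusted p = 0.277 with an estimated correlation).

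Markers of other cells were mostly higher in aPVAT controls, among them macrophages (17 of 19 higher, with C1qa at 0.998), lymphocytes (15 higher), sympathetic neurons (17 of 17 higher, with Npy at 2.19), Schwann cells (10 higher), endothelium (13 of 16 higher, with Vwf at 1.35), fibroblasts (9 higher), interferon response (29 of 29 higher, with Cxcl10 at 2.33), proliferation (13 higher) and extracellular matrix (22 higher, with Dcn at 1.18). Skeletal muscle genes (15 of 17 lower), red blood cell genes (5 of 5 lower) and partners of Prdm16 (13 of 31 lower, 3 higher) were lower. With an estimated correlation these calls were lost, with an adjusted p = 0.321 for macrophages and Schwann cells, 0.576 for lymphocytes, 0.533 for sympathetic neurons, 0.381 for endothelium and interferon response, 0.556 for fibroblasts, 0.298 for proliferation, 0.626 for extracellular matrix, 0.390 for skeletal muscle, 0.525 for red blood cells and 0.284 for partners of Prdm16. The fibroblast call was also lost without the 2 libraries with over 1% structural RNA (adjusted p = 0.0560), and the lymphocyte median went from 1.37 to 0.90 without aPVAT control 4. Lists that did not pass were lipolysis (0.214), creatine and calcium cycling (0.102), adipocytes of any kind (0.816), immediate early genes (0.252), thymocytes (0.906), smooth muscle (0.685), mesothelium (0.456), adrenal cortex (0.285) and kidney epithelium (0.579).

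**Figure D3:**
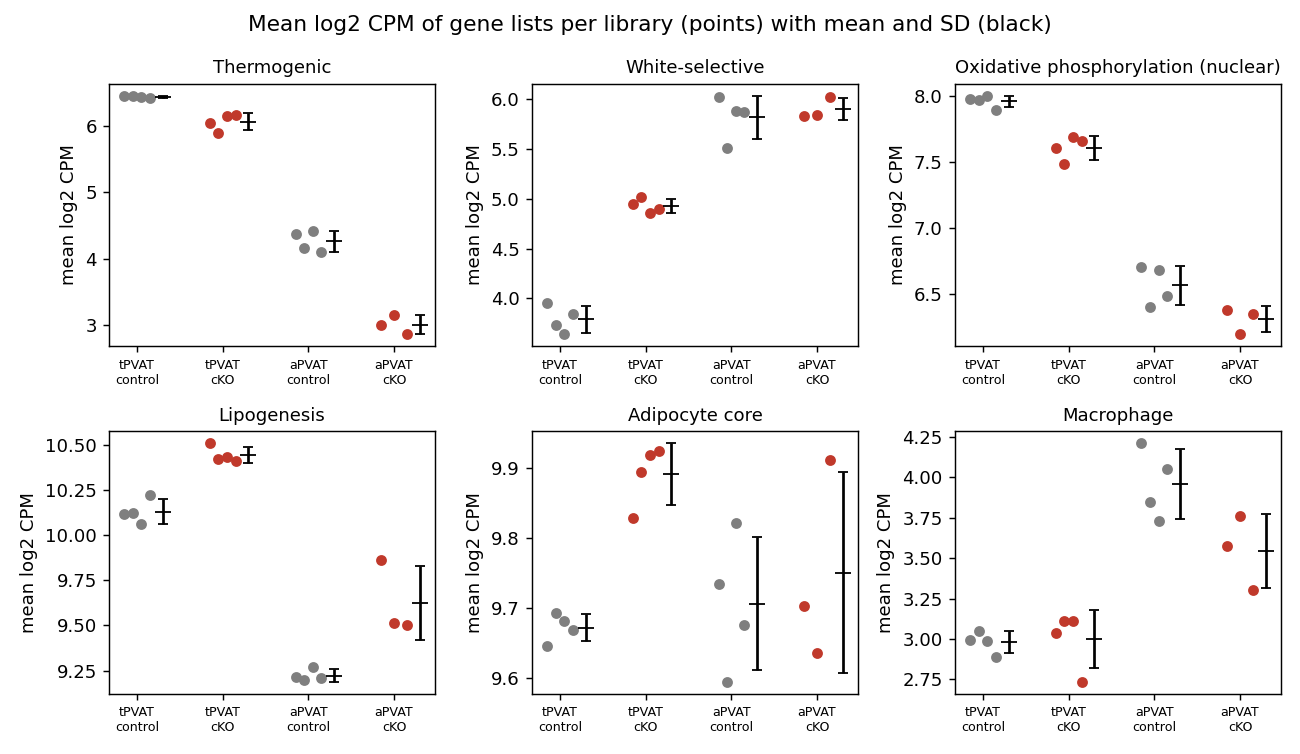
Mean log2 CPM of the members of 6 gene lists in the 15 libraries, with 1 point per library and the mean and SD of each group in black (axes do not start at 0). White-selective genes in tPVAT cKO lie between tPVAT controls and aPVAT, and thermogenic genes are lowest in aPVAT cKO.

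The depot comparison in cKO asked the same after the deletion. Ucp1 was lower in aPVAT by a wider margin (−7.74, SE 0.832), as were Cidea (−4.40, SE 0.155), Cpt1b (−5.82, SE 0.289) and Elovl3 (−5.25, SE 0.309). Hoxc10 (5.97) and Hoxa10 (4.61) were higher in aPVAT. Agt was higher by only 0.83 (SE 0.160, adjusted p = 0.000457), Retn by 1.29 (SE 0.122), and Qsox1 did not pass (0.03, SE 0.0832, adjusted p = 0.800). In all 10325 genes passed (52.6%), 5341 higher and 4984 lower, of which 4493 were higher and 4351 lower in controls also (1563 and 1363 expected), while 30 were called in opposite directions.

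Of the lists, 19 passed in cKO, against 20 in controls. Thermogenic genes were lower (31 of 34 lower, adjusted p = 2.66e-18, and adjusted p = 0.0356 with an estimated correlation), and posterior Hox genes (11 of 13 higher, adjusted p = 9.49e-08, and adjusted p = 0.0455 with an estimated correlation) and vasoactive genes (18 of 35 higher, adjusted p = 8.92e-05, and adjusted p = 0.0430 with an estimated correlation) higher. White-selective genes were higher for 15 of 20 and lower for 2 (adjusted p = 0.000562, and adjusted p = 0.284 with an estimated correlation). The calls of lymphocyte genes (adjusted p = 0.0352, and adjusted p = 0.680 with an estimated correlation) and red blood cell genes (adjusted p = 0.0467, and adjusted p = 0.576 with an estimated correlation) were lost without aPVAT cKO 1 (0.204 and 0.0670) or tPVAT cKO 1 (0.0569 and 0.0652), that of lymphocyte genes also without tPVAT cKO 2 (0.0833), and that of red blood cell genes also without aPVAT cKO 3 (0.0806), tPVAT cKO 3 (0.0575) or tPVAT cKO 4 (0.0588). Chance could not be excluded for the number of lists, which other splits matched in controls (20) and exceeded in cKO (21).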

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

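The tests on the number of libraries, on single aPVAT libraries, on the spread and on the share of adipocyte RNA were chosen after the result was seen, while the splits of the samples and the carry-over test were chosen before.

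Of 141 checks for a library far from the other 3 of its group, run only in groups of 4 libraries, 6 were met, where chance gives 7.05 (1 in 20). Structural RNA took 1.11% of the counts in aPVAT control 2, against 0.138% to 0.210% in the others. Elovl3 stood at 13.4 CPM in aPVAT control 1 (others 6.84 to 7.79). The 10 most abundant genes took 30.02% of the counts in tPVAT cKO 2 (others 32.7% to 33.2%). In tPVAT cKO 3 the mean log2 CPM was 1.46 for lymphocyte genes (others 0.54 to 0.69) and 0.56 for skeletal muscle genes (others 1.68 to 1.89). Adrenal cortex genes had a mean log2 CPM of −0.93 in tPVAT cKO 4 (others −0.72 to −0.70). The aPVAT cKO group, with 3 libraries, was not checked, so these counts do not cover it. In aPVAT cKO 4 structural RNA took 2.82% of the counts, against 0.265% and 0.127% in aPVAT cKO 1 and 3. Its total of 37.8 M counts was the smallest of all libraries.

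By the interaction test 14 named genes responded differently in the 2 depots, of which Ucp1 and Qsox1 were chosen for this contrast after their values were seen. The aPVAT effect minus the tPVAT effect (log2) was −4.38 for Agt, −4.22 for Ucp1, −3.73 for Apoc4, −2.75 for Apoc2, −2.62 for Mreg, −2.07 for Aldh3b2, −1.55 for Cidea, −1.47 for Pde1b, −1.42 for Retn, −1.26 for Adgrg2, −1.09 for Ccnd2, −0.88 for Alpl, −0.67 for Qsox1 and 2.85 for Gldn. The adjusted p of edgeR ranged from 1.45e-07 for Agt to 0.0256 for Ucp1, and the genes other than Ucp1 kept their side of the threshold in all fits with 1 of the 15 libraries left out. That of Ucp1 was 0.0555 without aPVAT control 3, 0.0615, 0.0558 and 0.0606 without tPVAT controls 1, 3 and 4, and 0.0581 without aPVAT cKO 1.

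The same difference passed for 12 lists. Its median was −0.77 for white-selective genes, −0.41 for thermogenic genes, −0.39 for macrophages, −0.16 for lipolysis, 0.22 for the mitochondrial genome, 0.34 for smooth muscle and 0.19 for endothelium. The other 5 lists were each lost in some fit. Nuclear respiratory chain genes (0.081) had an adjusted p of 0.0886 without aPVAT control 2 and 0.0692 with animal as block, and adipocytes of any kind (−0.13) one of 0.0603 without aPVAT cKO 3. Proliferation genes (−0.30) had an adjusted p of 0.117 without the 2 libraries with over 1% structural RNA. Lymphocyte genes (−0.63) had 0.247 without aPVAT control 4, 0.0560 without aPVAT cKO 3, 0.144 without aPVAT cKO 4 and 0.0876 without tPVAT cKO 3. Interferon response genes (−0.13) had 0.113 and 0.458 without aPVAT controls 1 and 2, 0.470 and 0.0749 without tPVAT controls 1 and 3, 0.408 without aPVAT cKO 1 and 0.0896 without tPVAT cKO 2. With an estimated correlation only the white-selective list passed (adjusted p = 0.0146).

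More genes changed with genotype in tPVAT (2367) than in aPVAT (301), and the smaller number of aPVAT cKO libraries is excluded as the whole cause, since with 1 tPVAT cKO library left out at least 1708 genes passed in tPVAT (without tPVAT cKO 1). A single doubtful aPVAT library is excluded too as the whole cause, since the aPVAT count reached at most 398 (without aPVAT control 2, against 161 without aPVAT cKO 1, and 362 without both libraries with over 1% structural RNA). Leaving out a library can itself lower the count, so a part played by 1 library is not excluded by it. The variance ratio given next also fell to 1.86 without aPVAT control 2. A larger spread between aPVAT libraries (median residual SD 0.144 against 0.110) is excluded as the whole cause, since the variance of the log2 fold changes net of their error was 3.21 times as large in tPVAT (0.0837 against 0.0260, 13421 genes). That ratio was 1.86 without aPVAT control 2, 5.74 without aPVAT cKO 1, and 1.80 to 5.89 over 56 pairs of fits with 1 library left out per depot. A different response of the depots to the loss of Prdm16 may account for the pattern, and this hypothesis was found and tested on the same data. Prdm16 itself fell less in aPVAT (21.4 to 26.8 CPM in controls, 14.7 to 18.3 in cKO) than in tPVAT (41.1 to 55.6 in controls, 21.2 to 23.8 in cKO). The difference between these falls missed the threshold of the interaction test. A smaller loss of Prdm16 in aPVAT was not tested as a cause and stays open.

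On the log2 scale white-selective genes rose more in tPVAT and thermogenic genes fell more in aPVAT. The control depots started from unlike levels of both lists. The second difference had an adjusted p = 0.0550 by camera with an estimated correlation. A camera p as small, in either direction, came from 6 of 100 draws of the genotype labels, the real one included. In tPVAT, white-selective genes rose by 0.97 beyond adipocyte core genes (difference in mean log2 CPM −5.22 ± 0.101 in cKO against −6.19 ± 0.161 in controls, n = 4 and 4, no overlap). The exact two-sided permutation p was 0.0286, the smallest that 8 libraries allow, without regard to the pairing by number. An equal rise of all adipocyte RNA is thus excluded as the whole cause of the rise. The white-selective list had already been seen to rise more than the core list, so this p is no independent support. Core genes rose by 0.212 themselves, and a change in the kinds of adipocytes was not tested. Tissue like tPVAT in the aPVAT control samples cannot be told apart from thermogenic genes of aPVAT itself, since the test on it decides nothing. By their Ucp1, the 4 control libraries would need a share of 11.6%, 5.81%, 11.7% and 5.84%, and 48.3%, 65.5%, 41.4% and 62.1% of 29 other genes at least 8-fold higher in tPVAT lay at or above the level needed (median level over needed 0.974, 1.22, 0.871 and 1.14). These genes were picked for a level in the aPVAT controls at least 8-fold below tPVAT, which holds them near or below the level needed in controls 1 and 3, so the shares and medians are largely set by that choice. The bound set before (under 90% excludes it) was met but was wrong by design for this reason and since a gene exactly at the level needed falls below it about as often as above, so the rule was changed after the value was seen, and the profile of any carried tissue is assumed. Those past a further cut on abundance in tPVAT controls were ranked by their level against the level needed. The lowest were Myh6 at 0.196 ± 0.0288 CPM where 8.51 would be needed, Gmpr at 5.15 ± 1.09 where 9.68 would be, and Elovl3 at 8.79 ± 3.11 where 15.7 would be. They are the extremes of a ranking, and Myh6 is a heart muscle gene, so they say little about carried fat. In aPVAT cKO the 29 genes had a median log2 fold change of −0.97 (14 lower, none higher), against −4.84 for Ucp1 (adjusted p = 0.0979 with only the 7 aPVAT libraries in the fit). That smaller fall goes against carried tissue as the only source of the 29 genes. It excludes no carried share, since the genes were picked by their control level. A gene with a level of its own in aPVAT would also fall less. Carried fat of another make-up and a difference between the depots stay open.

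Other splits of the same libraries into groups of the same sizes tested whether chance can be excluded. It can for the genes changed in tPVAT (2367, 1 of 35 splits as large, highest other 1), in aPVAT (301, 1 of 35, highest other 32) and between depots in controls (11122, 1 of 35, highest other 0). In tPVAT, where numbers pair the samples, the 7 other splits that also part all 4 pairs called 0 genes at most, while 24 part 2 pairs (highest 1) and 3 part none (highest 0). With the pairing kept, only the real split and these 7 remain, too few for a share under 0.05, so the shares of 35 for tPVAT, those of single lists included, hold only without regard to the pairing. Chance can also be excluded for the depots in cKO (10325, 1 of 35), where the highest other split called 6965. For the interaction (154, 2 of 100, highest other 396) and for genes called in both depots (227, 1 of 100, highest other 0) the draws decide less. They shuffled the genotype labels within each depot, without regard to the pairing by number, and so removed the genotype effects themselves. They thus test only against no genotype effect at all, and exclude chance for neither a difference nor an agreement between depots. The draw with 396 interaction genes swapped the label of every tPVAT library, so it parts the tPVAT libraries by genotype as the real labels do, and the genotype difference of tPVAT enters its count. Chance cannot be excluded for the number of lists in tPVAT (10, 18 of 35 as large, highest other 15), in aPVAT (13, 12 of 35, highest other 16), between depots in controls (20, 2 of 35, highest other 20), in cKO (19, 5 of 35, highest other 21) and for the interaction (12, 32 of 100, highest other 18). For single lists, 1 split of 35, the real one, had a camera p as small for white-selective and nuclear respiratory chain genes in tPVAT and for thermogenic, fatty acid oxidation and lipogenesis genes in aPVAT. Since 1 of 35 is the smallest share these splits allow and 29 lists were ranked in each contrast, some could come first by chance. No allowance was made for that. Chance cannot be excluded in this way for the other lists called in these genotype contrasts.

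In tPVAT as small a camera p came from 2 of 35 splits for thermogenic, lipogenesis and adipocyte core genes, 4 for fatty acid oxidation and endothelium, 5 for smooth muscle, 10 for the mitochondrial genome and 18 for sympathetic neurons. In aPVAT it came from 4 of 35 for partners of Prdm16, 5 for macrophages, 6 for the nuclear respiratory chain, 8 for fibroblasts, 9 for interferon response, 11 for immediate early genes and skeletal muscle, 12 for extracellular matrix, 14 for sympathetic neurons and 19 for lymphocytes. Of 100 draws for the interaction, 1 (the real one) was as small for white-selective and lipolysis genes, 6 for thermogenic genes, 12 for adipocyte core, proliferation and macrophage genes, 13 for endothelium, 18 for the mitochondrial genome, 22 for smooth muscle, 46 for lymphocytes, 56 for the nuclear respiratory chain and 63 for interferon response. Between depots only the real split of 35 was as small for thermogenic, nuclear respiratory chain, mitochondrial genome, fatty acid oxidation and posterior Hox genes in controls and in cKO, and for partners of Prdm16, white-selective and vasoactive genes in cKO, while the other called lists had 2 to 18 in controls and 2 to 17 in cKO.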

How the results depend on the processing

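The omission of the 2 libraries with over 1% structural RNA, the omission of mitochondrial genes and the agreement with only the groups compared were chosen after the result was seen. Of the values of named genes past the threshold, 284 kept their direction and their side of it under all alternatives run, and 41 fell short of it under at least one. Of those not past it, 63 kept to that, 23 passed under some alternative and 6 changed sign. Of the list calls, 58 held and 16 were lost somewhere, not counting the estimated correlation. With that, 1, 2, 3, 3 and 1 lists passed in the 5 contrasts in place of 10, 13, 20, 19 and 12, since by its construction the test widens where genes of a list vary together.

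With only the groups compared in the fit, 3726 genes passed in tPVAT (2041 higher, 2298 shared with the 2367) and 92 in aPVAT. Such a fit has fewer samples and takes the spread from 1 depot alone, where the fit of all 15 libraries takes it from both. With each depot fitted alone the median residual SD was 0.110 in tPVAT and 0.144 in aPVAT (13421 genes). Fewer samples alone would not account for a higher tPVAT count. Prdm16 in aPVAT was −0.55, the genes called in both depots numbered 73, and Pearson's r between depots was 0.467. With limma-voom weights 4080 genes passed in tPVAT (2351 shared). With DESeq2, 605 genes passed in aPVAT (299 of the 301 among them), 350 in the interaction and 417 in both depots. Without the low-count filter Pearson's r was 0.0693, as more genes near 0 entered. Except where said, the cause was not tested.

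With 1 library left out, the aPVAT count went from 161 (without aPVAT cKO 1) to 398 (without aPVAT control 2), and Prdm16 in aPVAT from −0.67 to −0.51 (without aPVAT cKO 3, adjusted p = 0.0591; without aPVAT cKO 1, −0.53 and 0.0692). Genes called in both depots numbered 129 (without aPVAT cKO 1) to 294 and 150 without aPVAT cKO 3, and Pearson's r was 0.239 (without aPVAT cKO 1) to 0.376. The tPVAT count went from 1708 to 1993, that between depots from 10242 to 11158 in controls and from 9090 to 10150 in cKO, and the interaction from 114 to 189.

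The values that changed sign were not past the threshold. In aPVAT without aPVAT cKO 3, Ckm was −0.43 (up to 2.97 over the left-out libraries) and Myh4 −1.37 (up to 6.53). With 1 library left out Adipoq was −0.15 to 0.071, Ppargc1a −0.20 to 0.18 and Lep −0.34 to 0.23. Adipoq was 0.0027 with only the groups compared and 0.0080 without mitochondrial genes. Ppargc1a was 0.15 and Lep 0.057 with weights per library, 0.033 and 0.026 with animal as block, Ppargc1a 0.0044 with number as block, and 0.27 without the 2 libraries with over 1% structural RNA. Between depots in cKO, Qsox1 was −0.035 without those 2 libraries and −0.035 to 0.10 with 1 left out.

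Blocking by number or by animal gave 2392 and 2271 genes in tPVAT, 312 and 308 in aPVAT, 11004 and 10765 between depots in controls, 10047 and 9753 in cKO, and 160 and 148 in the interaction. The counts of 2271 and 308 came from limma-voom with a random animal block (correlation 0.0217), so they change the tool along with the block. No limma-voom fit without block and weights was run beside them. Same-number correlations of residuals went down to −0.08 between control depots, −0.11 between cKO depots and −0.39 between aPVAT genotypes, so numbers were not taken to pair those. No other scaling moved the median of all genes by more than 0.0249 (log2). Lists under DESeq2, lists under a random animal block in the genotype contrasts, only the groups compared for the interaction, and Xist as a covariate were not run. The self-test recovered 26.9% (aPVAT) and 34.3% (tPVAT) of 1.5-fold changes. Its spread was estimated by depot without regard to genotype, so real genotype differences entered it, and it may understate what these libraries can show. In the data the 2367 genes called in tPVAT had a median absolute log2 fold change of 0.436.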

Other observations

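The gene groups and genes below, and the tests on neighbours of Adipoq and on calls with split controls, were chosen after the result was seen, so their counts are not independent evidence.

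Enzymes of cholesterol synthesis rose in both depots. In tPVAT 7 of 20 rose and none fell (adjusted p = 2.52e-05 by camera, and adjusted p = 0.208 with an estimated correlation), and in aPVAT 6 rose and none fell (adjusted p = 4.59e-17, and adjusted p = 0.122 with an estimated correlation). Sc5d rose by 0.72 in tPVAT and 0.73 in aPVAT, Msmo1 by 0.30 and 0.51, and Cyp51 by 0.69 and 0.92 (adjusted p = 0.0712 with only the 7 aPVAT libraries in the fit). Enzymes of the citric acid cycle fell in both, 16 of 17 in tPVAT (adjusted p = 2.22e-11, and adjusted p = 0.163 with an estimated correlation) and 10 in aPVAT (adjusted p = 1.17e-15, and adjusted p = 0.122 with an estimated correlation). This list shares 4 complex II genes with that of the respiratory chain. Peroxisome biogenesis genes went both ways in tPVAT (3 higher and 2 lower of 15, adjusted p = 0.411), and 2 rose in aPVAT (adjusted p = 0.00899, and adjusted p = 0.316 with an estimated correlation).

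Cardiac muscle genes fell in tPVAT, 5 of 12 lower and none higher (median −0.71, adjusted p = 0.000286, and adjusted p = 0.208 with an estimated correlation), among them Nppa (−2.38). In aPVAT none passed with edgeR (adjusted p of the list 0.265), and all 12 were lower in aPVAT than in tPVAT in controls and in cKO. Among vasoactive genes besides Agt, the prostaglandin E synthase Ptges rose by 2.28 in tPVAT. The nuclear receptor Esrrb of the list of Prdm16 partners rose by 2.93 there, while the coactivator Ppargc1b fell by 0.71.

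The changes of tPVAT cKO ran partly along the difference between the control depots. Of 1786 genes called in both contrasts, 1416 (79.3%) had the same sign, 496 higher in both (313 expected) and 920 lower in both (355 expected). Those expected counts take the contrasts as independent, but both share the tPVAT control libraries, which alone gave r = 0.502 in 100 simulations without any effect. With each contrast set against its own pair of these controls, 836 to 928 genes were called in both over 6 splits, and 77.7% to 86.5% of them had the same sign. With the controls split in that way, r across 13421 genes was 0.201 to 0.338 over 6 splits, against 0.302 unsplit. The covariance averaged 0.0615 over the splits, against 0.00995 from the shared libraries alone in the simulations.

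Near Adipoq on chromosome 16, 2 of 7 tested neighbours within 100 kb rose in both depots, the translation factor gene Eif4a2 (0.58 in tPVAT and 0.49 in aPVAT) and the predicted gene B630019A10Rik (1.97 and 1.61). In aPVAT neither passed with only the 7 aPVAT libraries in the fit (adjusted p = 0.0663 and 0.0522), nor did B630019A10Rik without aPVAT cKO 1 (0.0604) or 4 (0.0557) or without the 2 libraries with over 1% structural RNA (0.0687). Rfc4, between Eif4a2 and Adipoq and overlapping the end of Eif4a2 on the other strand, rose in aPVAT (0.56, adjusted p = 0.0347) but did not pass in tPVAT (0.28, adjusted p = 0.136; 0.0409 with weights per library). Its aPVAT call was lost without aPVAT control 1 (0.0536), 2 (0.0614), 3 (0.0690) or 4 (0.0512), without aPVAT cKO 1 (0.167) or 4 (0.106), without the 2 libraries with over 1% structural RNA (0.106), with only the 7 aPVAT libraries (0.145), without the low-count filter (0.0577), with weights per library (0.0585) and with the number as block (0.0639). Of 19484 windows around other genes, 53 (0.272%) held as many. These windows were not matched for their number of tested genes, overlap one another and include those around the neighbours of Adipoq. The region was also picked after its rise was seen, so the share is not a chance level for it. A candidate explanation is that the transgene, which holds the regulatory sequence of Adipoq, carries copies of neighbouring genes. The rise of Rfc4 goes with copies, though reads of Eif4a2 may be counted in it, while Adipoq itself (0.41 in tPVAT and −0.01 in aPVAT) and St6gal1 (−0.36 and −0.08) do not go with copies of the whole region in both depots, and an effect of Prdm16 on these genes stays open.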
